A study of Hydra vulgaris with 24 samples.

How the data were processed

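Drop-seq was read for 15 libraries: 9 from unsexed whole animals, 2 from females, 2 from males and 2 enriched for neurons by sorting of the reporter line nGreen. Preparation names came from the titles: D01 (whole animals 1 and 2), D02 (3, 4 and 5), D03 (6, female 1 and male 1, titled as spike-ins), D06 (7, female 2, male 2), D11 (8, from budding animals, and 9) and D12 (the sorted libraries). Tag-seq was read for 3 ectoderm and 3 endoderm pools and ATAC-seq for 3 replicates of whole animals.

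The deposited Drop-seq tables hold raw UMI counts per cell, unscaled, 1 on 37114 transcripts and 1 on 20781 rows for genome gene models; Bowtie2 2.2.6 is named in the submitters' processing notes. The deposited Tag-seq table holds expected counts per transcript, not scaled for depth, from RSEM 1.2.31 with Bowtie 1.1.2, per the submitters' processing notes. The deposited ATAC-seq list has a score that is constant at 1000; Trimmomatic 0.36, Bowtie2 2.2, Picard 2.17.8 and MACS2 2.1.1 are named in the submitters' processing notes. Genome build, cell filters and peak settings are not given in the sources used here. Gene symbols are those in the row names, which give the best database match of a transcript and its species.

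Cells were assigned to libraries by the prefix of their names. The transcriptome table held 27992 cells, the genome gene models covered 26265 cells, and 25776 cells were in both. Cells with 300 to 7000 detected genes and 500 to 50000 UMIs were kept (26922), and 1070 were left out. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 variable genes were chosen by normalised dispersion within each library, summed over libraries. With 40 principal components, 20 neighbours and seed 1, Leiden clustering at resolution 1 gave 51 clusters (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, Python 3.11.15). Scrublet, run per library, marked 48 cells (0.178%), so it has not worked here; possible doublets were kept.

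Clusters were named from marker lists for neurons, nematoblasts, nematocytes, gland cells, germline, sperm lineage, proliferating interstitial progenitors and epitheliomuscular cells of either layer. The lists were written before the data were examined, and the scoring rule was set after the clusters had been seen. For each cluster the 300 genes with the largest log2 ratio to all other cells were taken (5 CPM added, detected in at least 10% of the cluster, at least 100 UMIs). A class was given when its markers were enriched (hypergeometric p under 0.001, at least 3 markers). Clusters were left unnamed when their top 10 genes held more markers of another class, when 2 kinds of class were enriched, when they had under 50 cells, or when they were shallow without a marker in the top 10. Germline took precedence over progenitors where both were enriched. Ectodermal and endodermal names used the 50 leading Tag-seq genes of each layer and needed a summed epitheliomuscular log2 ratio above -0.5. The rule named 3 ectodermal, 2 endodermal, 2 germline, 1 sperm lineage, 6 gland, 1 nematoblast, 7 neuron and 2 progenitor clusters and 0 nematocyte clusters; 27 clusters with 9487 cells stayed unnamed.

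Gene tests used edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, two-sided, adjusted p under 0.05 after Benjamini and Hochberg), with libraries or pools as replicates and never cells. Expected counts were rounded. Drop-seq UMIs were summed per library over all cells or over the cells of a class with at least 10 cells. The sexed fit had preparation as a term, and the comparison of epithelial classes had library as a block. The common biological coefficient of variation was 0.268 in Tag-seq, 0.323 for sorted against whole-animal libraries, 0.337 within neuron-like cells, 0.232 in the sexed fit and 0.139 between epithelial classes. DESeq2 1.42.0 was the second tool. In simulated data with 200 changed genes, 2-fold changes were found in 18% and 4-fold changes in 83% of cases for Tag-seq, 12% and 57% for sorted against whole-animal libraries, 21% and 76% for males, 22% and 76% for females, 21% and 83% between the sexes, 100% and 100% between epithelial classes, and 22% and 95% within neuron-like cells. False calls made up 8.18%, 6.76%, 3%, 1.01%, 5.45%, 4.76% and 4.1% of all calls, in the same order. The real fits called far more than 200 genes in Tag-seq (4956), sorted libraries (7995), females (1086) and between epithelial classes (7689). Adjusted p-values depend on how many genes change, so these rates do not carry over to those fits.

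The 21 gene lists were written before the data were examined, as symbol patterns: collagens; laminins and other basement membrane glycoproteins; matrix metalloproteinases and astacins; digestive enzymes; lysosomal hydrolases; lipid transport; Wnt, BMP and TGF-beta, FGF and Notch pathways; forkhead, SOX and homeobox factors; ribosomal proteins; respiratory chain; glycolysis; proteasome; cell cycle; heat shock; axoneme; actomyosin; adhesion; and innate immunity. They were tested in Tag-seq with camera in limma 3.58.1 (correlation preset at 0.01, two-sided), with an estimated correlation and fry as alternatives. Genes were named by a rule also set before the data were examined: the 10 largest changes in each direction with a name, values that do not overlap between groups and an average log2 CPM of at least 4 (Tag-seq) or 5 (Drop-seq), and 3 genes per list. The reporters in Tag-seq and the brine shrimp matches were chosen after their values were seen. Class shares were compared with exact permutation tests over libraries of all preparations, and for the sexes also within D03 and D06 only, and list shares with exact sign-flip tests over libraries with at least 10 cells of the class (at least 6 libraries). The thinned alternative drew 500 UMIs per cell and asked for at least 3 neuron markers.

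Alternatives were another tool, another scaling, no filter, each library left out, replicate numbers as a block, other preparations, genome gene models, Leiden resolutions 0.5 and 2, all deposited cells, possible doublets left out, no precedence of germline, and peaks of at least 200 bases. Trajectories were not analysed here.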

Results

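The series measured gene activity in Hydra vulgaris, a freshwater polyp whose body wall is an ectodermal and an endodermal epithelium with interstitial cells between them. Single cells of strain AEP were profiled by Drop-seq, a droplet method that tags each messenger RNA molecule with a unique molecular identifier (UMI). The Drop-seq libraries comprised 9 from unsexed whole animals, 2 from females, 2 from males and 2 in which neurons of the reporter line nGreen had been enriched by flow sorting. The titles call female replicate 1 and male replicate 1 spike-ins, and what was added to what is not given in the sources used here. Bulk Tag-seq, which counts the ends of transcripts, covered 3 pools of body-column ectoderm and 3 of endoderm. Those pools came from a transgenic line that makes red fluorescent protein (RFP) in ectoderm and green fluorescent protein (GFP) in endoderm. Open chromatin was mapped by ATAC-seq in 3 whole-animal replicates of another laboratory strain.

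Depth differed between groups. Tag-seq libraries held 10.9, 8.32 and 11.4 M expected counts for ectoderm replicates 1, 2 and 3, and 8.19, 7.96 and 8.15 M for endoderm. Drop-seq libraries of whole animals held 8.8 to 35.2 M UMIs (mean 20.4 and SD 7.22 M, n = 9). Female libraries held 16.6 and 20.9 M, male libraries 17.7 and 16.2 M, and sorted libraries 2.47 and 3.88 M. Median UMIs per cell were 907 and 895 in the sorted libraries and 2261 to 15874 in whole animals. After filtering, 26922 of 27992 barcodes were kept for clustering. The series text states 24985 cells, and the filter behind that number is not given in the sources used here. All 45 pairs of libraries within a group differed by more than sampling noise, with a lowest chi-square per degree of freedom of 5.12. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

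The comparison of ectoderm with endoderm pools asked which genes distinguish the epithelial layers. The chymotrypsin CTRB_BOVIN (t20198aep) reached 3451 ± 621 CPM (counts-per-million; SD, n = 3) in endoderm and 13.7 ± 4.94 in ectoderm. Cathepsin L, CATL_DROME (t30017aep), reached 5965 ± 702 CPM in endoderm and 28.2 ± 9.66 in ectoderm. The Dickkopf-family gene DKK3_MOUSE (t22117aep), a relative of secreted Wnt modulators, lay at 337 ± 43.7 CPM in ectoderm and 5.42 ± 3.62 in endoderm. The reporters followed the labels, with RFP_DISSP (t12299aep) at 489 ± 71.7 CPM in ectoderm against 9.6 ± 4.53 in endoderm, and GFP_AEQVI (t19256aep) at 6.89 ± 2.59 against 829 ± 353.

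Among 36 tested pancreatic-type digestive enzymes, 28 were higher in endoderm, 4 higher in ectoderm and 4 did not pass; adjusted over the list alone, the counts were 28 and 5. The elastase CEL2A_RAT (t15836aep) had a log2 fold change of ectoderm over endoderm of -8.25 (SE 0.374, edgeR adjusted p = 1.34e-09), and the carboxypeptidase CBPB1_PIG (t3565aep) one of -7.36. This list passed limma's camera test (adjusted p = 7.57e-09), and it was the only list to do so with an estimated correlation (adjusted p = 0.0473). Of 42 lysosomal hydrolases 31 were higher in endoderm and 9 in ectoderm, the same counts as adjusted over the list alone. The cholesterol carrier NPC2_DROME (t32852aep) rose from 2.29 ± 0.78 CPM in ectoderm to 739 ± 172 in endoderm, and cathepsin Z, CATZ_RAT (t11413aep), from 1.68 ± 0.415 to 462 ± 24. The hexosaminidase HEXA_HUMAN (t21339aep) went the other way, at 34.6 ± 5.18 CPM in ectoderm and 0.370 ± 0.359 in endoderm. For the lysosomal list the camera adjusted p = 5.41e-06 became an adjusted p = 0.359 with an estimated correlation.

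Matrix genes were also mostly endodermal. Of 8 collagens 6 were higher in endoderm and 1 in ectoderm, by both adjustments, and the list median was -6.07. CO4A2_ASCSU (t17889aep), a chain of basement membrane collagen, stood at 1568 ± 444 CPM in endoderm against 19.8 ± 3.19, and the fibrillar collagen CO1A2_MOUSE (t296aep) at 1663 ± 475 against 24.7 ± 4.4. The collagen list had a camera adjusted p = 0.000654, and adjusted p = 0.359 with an estimated correlation. Laminins and related glycoproteins split into 9 higher in endoderm and 6 higher in ectoderm of 15 (the same over the list alone), and the list did not pass (camera adjusted p = 0.121). LAMA_DROME (t9355aep) had a log2 fold change of -4.20 and AGRIN_CHICK (t2352aep), a heparan sulfate proteoglycan, one of -6.96. Of 48 matrix metalloproteinases and astacins 31 were higher in endoderm and 12 in ectoderm, or 31 and 13 adjusted over the list alone. The astacin NAS4_CAEEL (t14211aep) fell from 85.6 ± 2.68 CPM in endoderm to 0.183 ± 0.25 in ectoderm, and the meprin MEP1B_MOUSE (t20535aep) from 829 ± 94.7 to 3.84 ± 0.369. This list had a camera adjusted p = 9.73e-06, and adjusted p = 0.199 with an estimated correlation.

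Axonemal and intraflagellar genes leaned to endoderm, with 43 of 90 higher there and 5 higher in ectoderm (47 and 5 adjusted over the list alone). RSPH1_HUMAN (t34431aep), a radial spoke protein, lay at 30.7 ± 3.09 CPM in endoderm and 0.404 ± 0.142 in ectoderm. The list's camera adjusted p = 1.92e-06 became an adjusted p = 0.199 with an estimated correlation. Of 50 innate immunity genes 22 were higher in endoderm and 6 in ectoderm (23 and 6 adjusted over the list alone), with camera adjusted p = 0.0237 and adjusted p = 0.199 with an estimated correlation. Its members included CASPA_HUMAN (t26312aep), which matches a protease of cell death and stood at 546 ± 114 CPM against 19.1 ± 3.2. Cell cycle genes were the only list that camera called higher in ectoderm. Of 32 members 16 were higher and 0 lower by edgeR (17 and 1 adjusted over the list alone). The ribonucleotide reductase RIR2_HUMAN (t8647aep) had 45.4 ± 7.99 CPM in ectoderm and 1.78 ± 0.74 in endoderm, and the dUTPase DUT_HUMAN (t12648aep) had a log2 fold change of 4.71. That list had a camera adjusted p = 0.00216, and adjusted p = 0.359 with an estimated correlation.

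Signalling and transcription factor lists did not pass camera, and all but FGF held edgeR calls on both sides. By fry, Notch passed towards ectoderm (adjusted p = 0.000971). FGF (fry adjusted p = 0.000627), BMP and TGF-beta (0.0013) and Wnt (0.00161) passed towards endoderm, and the transcription factors did not pass (0.0685). Notch genes counted 7 higher in ectoderm and 3 higher in endoderm of 12 (the same over the list alone), with a camera adjusted p = 0.0842. The Notch ligand DLL1_XENLA (t27765aep) had a log2 fold change of 6.01, and the transcripts matching NOTC1_DANRE split, t30599aep at 4.07 and t4124aep at -5.53. In the Wnt list 3 of 17 were higher in ectoderm and 5 in endoderm (the same over the list alone; camera adjusted p = 0.481), among them the Wnt potentiator RSPO2_HUMAN (t12100aep) at -6.74 and the receptor FZD8_RAT (t15331aep) at -5.55. The BMP and TGF-beta list had 2 and 6 of 15 (3 and 6 adjusted over the list alone; camera adjusted p = 0.19), with the myostatin match GDF8_CAPIB (t9440aep) at -7.09. FGF genes had 0 higher in ectoderm by edgeR and 6 higher in endoderm of 11 (1 and 6 adjusted over the list alone; camera adjusted p = 0.138), including the receptor FGFR2_XENLA (t3456aep) at -3.69. Of 37 forkhead, SOX and homeobox genes 15 were higher in ectoderm and 10 in endoderm, the same over the list alone (camera adjusted p = 0.575, with a median of -0.18 and a mean of 0.41). PAX2A_DANRE (t9974aep) stood at 136 ± 12.2 CPM in ectoderm against 2.19 ± 0.723, FOXN4_DANRE (t12948aep) at 44.6 ± 1.16 against 0.362 ± 0.333, and SOX14_XENTR (t25403aep) had a log2 fold change of -6.92. FOX1_CAEEL (t16997aep), with the largest named increase in ectoderm at 9.03, is an RNA-binding protein that matched this list by its name only.

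Contractile genes divided between the layers, with 15 of 30 actomyosin members higher in ectoderm and 12 higher in endoderm (16 and 13 adjusted over the list alone; camera adjusted p = 0.426). The myosin light chain match MYL6B_HUMAN (t9585aep) lay at 297 ± 100 CPM in ectoderm and 4.99 ± 2.05 in endoderm. MLRP2_ACRMI (t35994aep), at 4.89 ± 1.9 and 444 ± 33.6, matches a coral extracellular protein and entered the list by its name only. Adhesion genes had 5 and 8 of 32 (the same over the list alone; camera adjusted p = 0.573), with the gap junction protein INX3_DROME (t27824aep) at 519 ± 102 CPM in ectoderm against 27.9 ± 4.39. The lipid list had 3 and 3 of 13 (the same over the list alone; camera adjusted p = 0.717, with a median of 0.21 and a mean of -0.67). One of its members lower in ectoderm, FRIH_TREBE (t31900aep) at -7.11, is a ferritin, which stores iron. Heat shock and immediate early genes had 3 and 4 of 11 (the same over the list alone; camera adjusted p = 0.575, with a median of -0.02 and a mean of 1.02), including JUN_AVIS1 (t17964aep) at 5.77.

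Housekeeping lists moved little in the pools. Mitochondrial respiratory chain genes counted 3 of 52 higher in ectoderm and 0 lower by edgeR (0 and 0 adjusted over the list alone; camera adjusted p = 0.563). Ribosomal protein genes counted 0 higher and 2 lower of 79, by both adjustments (camera adjusted p = 0.575, with a median of 0.07 and a mean of -0.07). The lower ones were RL40_CRYNJ (t26362aep), a ubiquitin fusion, at -7.83, and RLA2_ARTSA (t3342aep) at -7.19, with 87.9, 9.45 and 12.6 CPM in endoderm replicates 1, 2 and 3 and at most 0.585 in ectoderm. Glycolysis had 0 and 3 of 13 (the same over the list alone; camera adjusted p = 0.575), with hexokinase HXK2_DROME (t22801aep) at -1.64. The proteasome list had 3 higher and 2 lower of 41 (1 and 2 adjusted over the list alone; camera adjusted p = 0.453). Its largest shifts, PRSS8_RAT (t7388aep) at -7.71 and PRS38_MOUSE (t18245aep) at 6.96, are serine proteases outside the proteasome.

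Markers of other cell types moved with the layers as well. Of 72 gland cell markers 51 were higher in endoderm and 14 in ectoderm (51 and 16 adjusted over the list alone). The gland list includes the digestive enzymes and NAS astacins counted above. The sperm lineage list likewise shares dyneins and tektins with the axonemal list. Nematoblast markers leaned to ectoderm, 10 against 4 of 20 (10 and 5 over the list alone), and that list also holds DKK3, PAX2A and FOXN4. Nematocyte markers counted 20 against 5 of 57 (21 and 5 over the list alone), and proliferating progenitor markers 14 against 2 of 30. Neuron markers counted 16 higher in ectoderm and 29 higher in endoderm of 86, germline markers 4 and 4 of 23, sperm lineage markers 1 and 27 of 65, and epitheliomuscular markers 12 and 15 of 38.

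**Figure D1:**
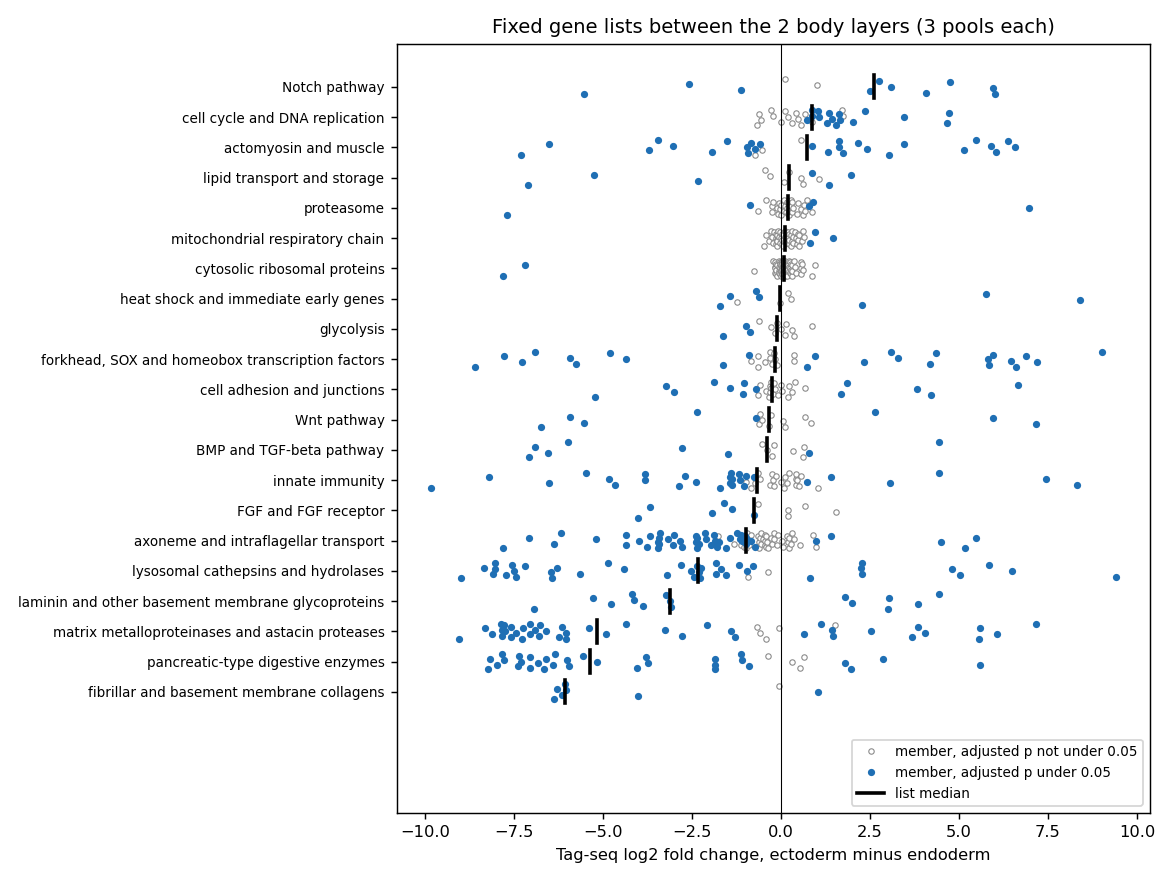
Tag-seq log2 fold change of ectoderm over endoderm (horizontal axis) for the members of 21 gene lists (vertical axis), 3 pools per layer. Filled points have an edgeR adjusted p under 0.05 and bars mark list medians, from -6.07 for collagens to 2.62 for Notch genes.

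In all, edgeR's quasi-likelihood test called 2320 of 12387 genes higher in ectoderm and 2636 higher in endoderm at an adjusted p under 0.05. The layers' values did not overlap in 6366 genes, against the 10% that chance gives for 3 pools against 3. Transcripts matching brine shrimp mitochondrial genes were uneven within endoderm, with NU3M_ARTSF (t694aep) at 342 CPM in replicate 1 and 10.6 and 25.5 in replicates 2 and 3.

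Drop-seq allowed the same layer question in single cells, with ectodermal and endodermal epithelium-like cells of the same 13 unsorted libraries compared within each library. These classes had been named with the leading Tag-seq genes of each layer, so they are not independent of the pools. The ectodermal-like cells were marked by the tropomyosin TPM1_HYDVU (t20172aep), at 196 ± 55.3 CPM against 1.56 ± 1.11 (SD, n = 13 libraries), and by PRPX_HORVU (t12447aep), at 565 ± 270 against 2.29 ± 1.12. The arginase ARGI_LITCT (t14594aep) reached 74.9 ± 42.1 CPM against 0.127 ± 0.15, and the sulfotransferase G3ST3_MOUSE (t27557aep) 127 ± 55.2 against 0.446 ± 0.38. Endodermal-like cells held more GDF8_CAPIB (t9440aep), 401 ± 112 CPM against 1.74 ± 0.944, more SOX14_XENTR (t25403aep), 87.8 ± 36.6 against 0.211 ± 0.201, and more of the cathepsin CATL_SARPE (t22763aep), 1521 ± 787 against 6.72 ± 5.25.

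Collagens were again mostly endodermal, 7 of 8 higher in endodermal-like cells and 1 in ectodermal-like cells, the same over the list alone; CO4A2_ASCSU (t17889aep) stood at 1004 ± 319 CPM against 10.6 ± 7.06. Of 42 lysosomal genes 32 were higher in endodermal-like and 7 in ectodermal-like cells (the same over the list alone), and of 78 axonemal genes 57 and 9 (58 and 9 over the list alone). Digestive enzymes counted 17 and 2 of 23 (the same over the list alone), with the elastase CEL2A_PIG (t4539aep) at -6.41. CTR2_HUMAN (t10262aep), at -6.16, is an amino acid transporter that entered by its name. The median of this list was only -1.3, against -5.36 over the 36 members tested in the pools. Metalloproteinases and astacins counted 21 and 8 of 31 (the same over the list alone), with a median of -0.978 against -5.16 over 48 in the pools. Adhesion genes counted 17 higher in ectodermal-like and 4 higher in endodermal-like cells of 27 (the same over the list alone), with ZO1_CANLF (t29625aep), a junction scaffold, at 1.25. In the Wnt list 3 of 17 were higher in ectodermal-like and 10 in endodermal-like cells, in the BMP and TGF-beta list 3 and 10 of 17, and among FGF genes 4 and 7 of 14 (all the same over the list alone). DLL1_XENLA (t27765aep) and WNT8_XENLA (t23521aep) were higher in ectodermal-like cells, with log2 fold changes of 7.67 and 4.92. RSPO2_HUMAN (t12100aep), at -6.45, was higher in endodermal-like cells. Notch genes counted 4 and 4 of 10 (5 and 4 over the list alone). Ribosomal protein genes counted 59 higher in ectodermal-like and 3 in endodermal-like cells of 79 (60 and 3 over the list alone), by a median of only 0.105. Proteasome genes counted 29 and 6 of 40 (median 0.203) and respiratory chain genes 19 and 17 of 51, the same over each list alone.

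The edgeR fit with library as a block called 3929 of 10333 genes higher in ectodermal-like and 3760 higher in endodermal-like cells, and 4709 genes had the same sign in every library. Across the 9050 genes tested in both assays, Pearson's r of the log2 fold changes was 0.872 and Spearman's rho 0.679, with 153 genes that had served to name the clusters left out. Of 3042 genes called in both assays, 2836 (93.2%) had the same sign and 206 the opposite sign. These correlations are across genes, which are not independent replicates. The epithelial classes had been named with leading Tag-seq genes. The direction of this agreement was thus favoured in advance, also with those genes left out. Different clusters made up most of the ectodermal-like class: cluster 3 held 68.8% of it in whole animals, and cluster 8 held 72.0% in females and 72.4% in males.

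**Figure D2:**
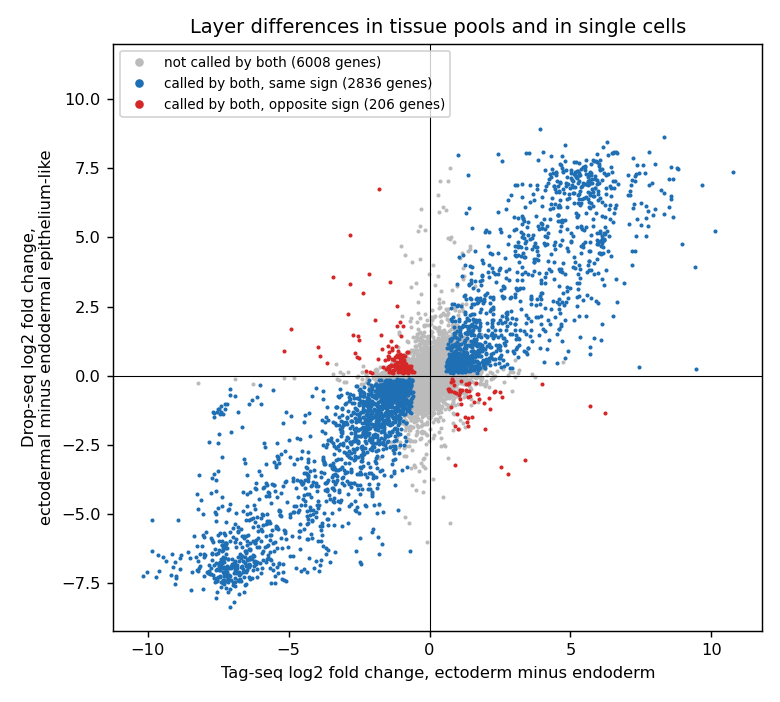
Log2 fold change of ectoderm over endoderm pools in Tag-seq (horizontal axis) against that of ectodermal over endodermal epithelium-like cells in Drop-seq (vertical axis), 1 point per gene over 9050 genes. Genes called in both assays are coloured, 2836 with the same sign and 206 with opposite signs.

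Sorting of nGreen animals was meant to enrich neurons, and the sorted libraries were compared with the 9 unsexed whole-animal libraries. Neuron-like cells made up 44.3% ± 1.98 (SD, n = 2 libraries) of sorted cells and 1.64% ± 1.28 (n = 9) of whole-animal cells, a difference of 42.7 percentage points (exact two-sided permutation test, p = 0.0182, the smallest that 55 regroupings allow). Proliferating interstitial progenitor-like cells were at 22.3% ± 0.316 in sorted and 12.9% ± 3.94 in whole-animal libraries, and gland-like cells at 8.87% ± 0.535 and 8.85% ± 2.7. Ectodermal epithelium-like cells stood at 0.114% ± 0.0521 against 15.7% ± 3.18, and endodermal ones at 0.368% ± 0.0238 against 21.1% ± 2.14. Cluster 2 held 74.3% of the progenitor-like cells of whole animals and cluster 5 held 70.6% of those of sorted libraries. Among its 300 leading genes cluster 5 had 14 neuron and 10 progenitor markers, and its sorted cells held GFP at 1430 CPM on genome gene models, against 1170 to 1840 in the 6 neuron-like clusters above the mean of sorted cells. These shares come from sorted suspensions of lower depth (907 and 895 median UMIs per cell), in which only cells with at least 500 UMIs were kept.

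Clusters 25 and 33, left unnamed although enriched for neuron markers, held 8.93% ± 0.77 and 5.96% ± 0.184 of sorted cells. In whole animals they held 0.440% ± 0.371 and 0.385% ± 0.257, in females 0.437% and 0.546%, and in males 0.305% and 0.483%. Cells with UMIs of at least 3 neuron markers made up 52.0% ± 4.41 of sorted and 24.0% ± 7.49 of whole-animal cells after thinning to 500 UMIs (exact two-sided permutation test, p = 0.0182), and 86.7% ± 2.79 and 94.7% ± 8.16 at full depth (p = 0.164). In the thinned cells, endodermal epithelium-like cells reached 27.6% in whole animals, at a median depth of 8994 UMIs before thinning. Neuron-like cells reached 76.5% at 1760 UMIs. The markers are matches by name, and 29 of 86 were higher in endoderm pools, against 16 higher in ectoderm pools.

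Counts were also summed over all cells of a library. LWA_HYDEC (t11055aep), an LWamide precursor, reached 6123 ± 844 CPM (SD, n = 2) in sorted and 137 ± 89 (n = 9) in whole-animal libraries. The RFamide precursor match PRFA_POLPE (t3809aep) reached 4820 ± 1750 against 102 ± 46.9, the calcium-binding protein CAB32_DROME (t22111aep) 1001 ± 23.5 against 18.0 ± 7.36, and the tubulin TBA1C_HUMAN (t14440aep) 1274 ± 149 against 29.6 ± 15.2. The nGreen reporter itself, GFP_AEQVI (t19256aep), stood at 313 ± 32.6 CPM against 0.653 ± 0.348, a log2 fold change of 8.86 (SE 0.366, edgeR adjusted p = 4e-09). Among the genes that fell furthest, the sulfotransferase G3ST3_MOUSE (t27557aep) had a log2 fold change of -8.60 and the torsin TOR1A_MACFA (t38653aep) one of -7.40.

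Of 156 neuron markers 70 were higher in sorted libraries, 37 lower and 49 did not pass (71 and 37 adjusted over the list alone). Of 44 epitheliomuscular markers 28 were lower and 5 higher (28 and 6 over the list alone). Lysosomal genes counted 29 lower and 3 higher of 46, by both adjustments, with CATL_DROME (t30017aep) at 299 ± 52.2 CPM against 4627 ± 684. Innate immunity genes counted 35 lower and 2 higher of 62 (the same over the list alone), with TRAF5_MOUSE (t22643aep) at -3.74. The collagens had 6 of 8 lower and 0 higher by edgeR (the same over the list alone), and FGF genes 16 of 29 lower and 1 higher (17 and 1 over the list alone). Adhesion genes split 21 lower and 8 higher of 39 (the same over the list alone): the innexin INX3_DROME (t8891aep) rose to 192 ± 8.94 CPM from 5.89 ± 4.4, and CNTP5_CANLF (t15665aep), a contactin-associated protein, had a log2 fold change of 3.11. Axonemal genes had 31 higher and 19 lower of 138 (31 and 18 over the list alone), and transcription factors 12 and 15 of 50 (12 and 16 over the list alone), with SOX14_DANRE (t21322aep) at 2.55 and HXB1_MACNE (t1602aep) at -5.07.

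The fit called 3831 of 18441 genes higher and 4164 lower in sorted libraries. Without neuron-enriched replicate 1 the counts were 2387 and 2738, and without replicate 2 they were 2427 and 2621. Both sorted libraries belong to a preparation with no unsorted library, so sort and preparation cannot be told apart.

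Within neuron-like cells, 203 of 2579 genes differed between sorted and whole-animal libraries, 65 higher and 138 lower. GFP_AEQVI (t19256aep) was at 772 ± 107 CPM in sorted and 8.41 ± 13.3 in whole-animal neuron-like cells (n = 2 and 7 libraries), and the tubulin TBB_HALDI (t16977aep) at 577 ± 57.8 against 172 ± 144. The receptor GRM3_MACFA (t6510aep), a metabotropic glutamate receptor match, had a log2 fold change of 1.87, and the forkhead factor FOXI2_XENTR (t1509aep) one of 1.38. Of 6 collagens 3 were lower (4 adjusted over the list alone) and of 5 metalloproteinases and astacins 2 (2), with 0 higher in either list. CATL_DROME (t30017aep) lay at 14.4 ± 6.07 CPM against 1641 ± 1550, TRY3_SALSA (t34424aep), a trypsin match, at 403 ± 65.5 against 2784 ± 1660, and CO4A2_ASCSU (t17889aep) at 14.8 ± 2.01 against 183 ± 141. Of 19 lysosomal genes 8 were lower and 0 higher by edgeR (13 and 0 adjusted over the list alone). Free RNA in the droplets was not estimated, and endodermal epithelium-like cells made up 0.368% of sorted and 21.1% of whole-animal cells. Only 9 genes passed without neuron-enriched replicate 1 and 14 without replicate 2, and the count was 1715 without Scrublet's calls and 62 without the highest 5% of its scores. Both alternatives also clustered and named the cells anew, which gave 2261 and 1771 neuron-like cells instead of 1916.

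Male and female libraries were compared with the unsexed ones to find genes and cells of the germline. With preparation as a term, the fold changes of either sex rest on D03 and D06, each with 1 unsexed library. The spread behind the p-values also comes from unsexed libraries within D01, D02 and D11, preparations that hold no sexed library. The CPM means and SD beside them cover all 9 unsexed libraries and can differ from the fold changes. Male libraries contained linker histones far above whole animals: H10_HUMAN (t22193aep) lay at 1016 ± 650 CPM (SD, n = 2) against 2.94 ± 2.6 (n = 9), a log2 fold change of 8.23 (SE 1.43, edgeR adjusted p = 0.0134), and H10A_XENLA (t38683aep) at 1657 ± 1450 against 4.29 ± 5.31. KI67_HUMAN (t16068aep), a marker of cycling cells, was at 67.2 ± 18 CPM against 38.5 ± 10.7, and the centromeric histone CENPA_MILFA (t15364aep) had a log2 fold change of 1.27.

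In males, 15 of 129 axonemal genes were higher and 0 lower (36 and 0 adjusted over the list alone), with the tektin TEKT1_CANLF (t6401aep) at 1.71 and the dynein chain DYI2_HELCR (t23364aep) at 2.2. Sperm lineage markers, some of them axonemal dyneins and tektins already counted, had 14 of 95 higher and 0 lower. Adjusted over the list alone the counts were 27 and 0. Germline markers had 7 of 34 higher and 0 lower (10 and 1 over the list alone). No member of the cell cycle list passed over all genes, and 9 of 35 were higher adjusted over the list alone. KI67_HUMAN (t16068aep), which passed, is not in that list. Digestive enzymes had 3 of 44 lower and 0 higher (4 and 0 over the list alone), among them the elastase CEL3B_MOUSE (t18337aep) at -1.81. The BMP and TGF-beta list had 3 of 19 lower and 0 higher (3 and 1 over the list alone), led by GDF8_CAPIB (t9440aep) at -1.97, and the Wnt antagonist SFRP4_RAT (t23426aep) was at -1.39.

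Female libraries were marked by PERI_HYDVU (t11117aep), the Hydra antimicrobial peptide periculin, at 3332 ± 2740 CPM (SD, n = 2) against 21.5 ± 22.4 (n = 9), a log2 fold change of 9.20 (SE 1.67, edgeR adjusted p = 0.00964). The transcription factor MYC_ASTRU (t26367aep) reached 266 ± 182 CPM against 35.6 ± 3.98, and the importin IMA1_XENLA (t5156aep), a nuclear import receptor, 120 ± 95.2 against 16.1 ± 3.16. Genes lower in females included NPC2_DROME (t32130aep), at 110 ± 55.6 CPM against 491 ± 224, the Hydra antimicrobial peptide HYDMA_HYDVU (t27530aep), at 84.2 ± 42.6 against 224 ± 138, and GDF8_CAPIB (t9440aep), with a log2 fold change of -2.42.

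In females, 12 of 44 digestive enzymes were lower and 0 higher (16 and 1 adjusted over the list alone), with CTRB_BOVIN (t20198aep) at -1.37 and TRY3_SALSA (t34424aep) at -1.38. Gland markers, a list that includes every digestive enzyme, had 18 of 87 lower and 0 higher (29 and 2 over the list alone). Of 46 lysosomal genes 11 were lower and 1 higher (20 and 2 over the list alone). CATL_DROME (t30017aep) was at -1.36, and the glucosidase match LYAG_RAT (t36826aep) at 4.85. These sums cover all cells, and endodermal epithelium-like cells made up 9.41% of female and 21.1% of whole-animal cells. Cell cycle genes had 6 of 35 higher and 0 lower (11 and 1 over the list alone), with the kinase CDK2_HUMAN (t13516aep) at 1.50 and DUT_HUMAN (t12648aep) at 1.42. Germline markers had 4 of 34 higher and 0 lower (9 and 0 over the list alone), and innate immunity genes 1 of 62 higher and 6 lower (2 and 6 over the list alone), with TRAF5_MOUSE (t22643aep) at -1.26.

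The direct test of males against females called 140 genes higher and 22 lower of 17410. The centrin CETN1_BOVIN (t10102aep) lay at 110 ± 38.3 CPM in males against 39.6 ± 11.3 in females (edgeR adjusted p = 0.0424). Axonemal genes were higher in 15 of 129 cases and lower in 0 (66 and 4 adjusted over the list alone), including the radial spoke protein RSPH3_HUMAN (t5254aep) at 1.43 and IQCG_HUMAN (t2603aep) at 1.50. Sperm lineage markers had 14 of 95 higher and 0 lower (44 and 3 over the list alone). The axonemal and sperm lineage lists share dyneins and tektins, so their counts are not separate. MYC_ASTRU (t26367aep) fell to 57.3 ± 23.1 CPM in males from 266 ± 182 in females, and the homeobox factor IRX6_HUMAN (t16018aep) had a log2 fold change of -1.46. NPC2_DROME (t32130aep), at 1.31, and CTRB_BOVIN (t20198aep), at 0.94, were higher in males.

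Against whole animals, the fit called 255 genes higher and 83 lower in males and 474 higher and 612 lower in females, with 2708 and 3944 genes at an unadjusted p under 0.05. Within preparations D03 and D06 alone, which each hold 1 library of either sex and 1 unsexed library, edgeR called 4 and 0 genes in males, 0 and 0 in females, and 0 between the sexes, with 1749, 2603 and 1150 genes at an unadjusted p under 0.05. DESeq2, run on all 13 libraries, called 427 and 299 genes in males, 692 and 934 in females and 416 between the sexes. Single libraries moved these counts, and a group then held 1 library whose spread was assumed to equal that of the others. Without female replicate 1 there were 960 genes higher in females and 1196 different between the sexes, and without female replicate 2 there were 204 and 24, with 218 lower in females. Without male replicate 1 there were 31 genes lower in males and 342 different between the sexes, and without male replicate 2 there were 28 and 13, with 113 higher in males. Counts higher and lower in males were 483 and 198 without female replicate 1, and 476 and 176 without female replicate 2.

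Cell shares were read the same way. Sperm lineage-like cells made up 17.4% ± 9.93 of male libraries (10.4% and 24.4%) and 0.26% ± 0.269 of whole-animal libraries, a difference of 17.2 percentage points (exact two-sided permutation test, adjusted p = 0.0364 over 4 tests). In females they were at 1.29% ± 1.58 (adjusted p = 0.121). Germline-like cells made up 21.3% ± 16.5 of female libraries (9.61% and 32.9%) and 2.2% ± 1.3 of whole-animal libraries, a difference of 19.1 percentage points (exact two-sided permutation test, adjusted p = 0.0364). In males they were at 3.52% ± 4.21 (adjusted p = 0.455). Each raw p of 0.0182 is the smallest that 55 regroupings allow, and these exchange libraries across preparations. Exchanged only within D03 and D06, 4 arrangements exist and the smallest p is 0.5; sperm lineage-like cells stood there at 10.4% and 24.4% in males against 0.0502% and 0.705% in unsexed libraries, and germline-like cells at 9.61% and 32.9% in females against 0.854% and 3.82%. Cluster 14 held 97.4% of germline-like cells in whole animals and cluster 21 held 90.6% in females, and cluster 21 had its strongest marker enrichment for proliferating progenitors. When such clusters were not given to the germline, the female difference was 0.0849 percentage points (exact two-sided permutation test, adjusted p = 0.927), and the adjusted p of the male sperm lineage-like difference was 0.0727. Endodermal epithelium-like cells were at 9.41% ± 1.72 in females and 7.91% ± 3.97 in males against 21.1% ± 2.14 in whole animals.

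**Figure D3:**
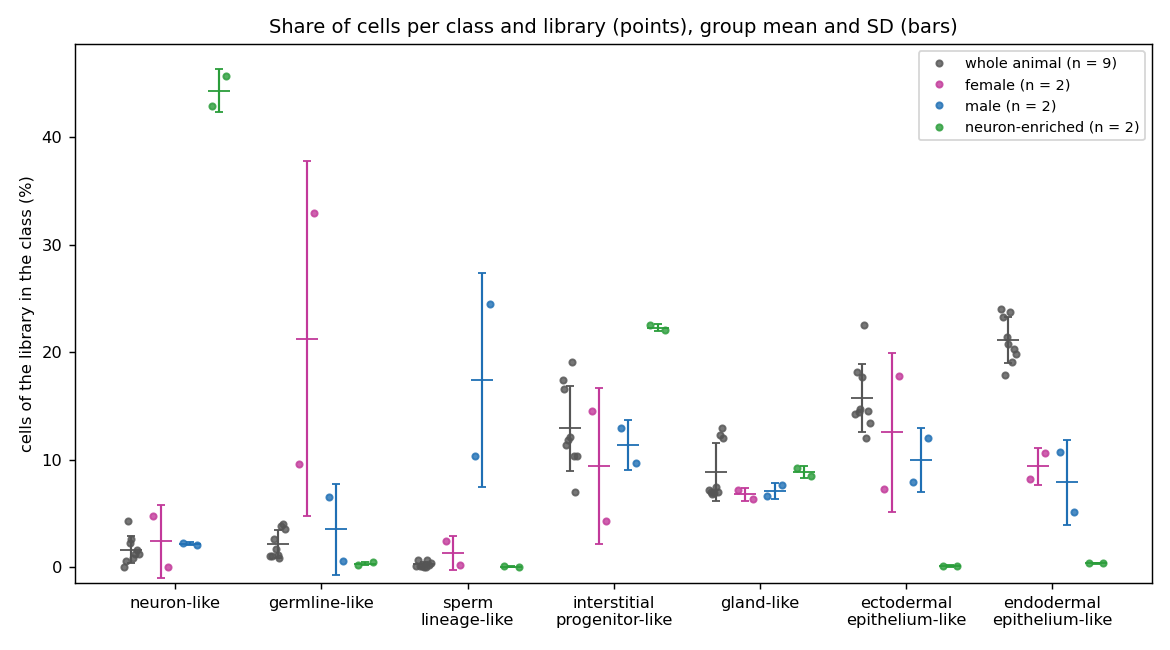
Percent of the cells of each library (vertical axis) in 7 named cell classes (horizontal axis), 1 point per library with group means and SD as bars, for 9 whole-animal, 2 female, 2 male and 2 neuron-enriched libraries. Neuron-like cells lie at 42.9% and 45.7% in the sorted libraries and at most 4.28% in whole animals.

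Gene lists were finally compared between classes within the 13 unsorted libraries, as the percent of a class's UMIs against that in all other cells. Nematoblast-like cells, precursors of stinging cells, gave Notch genes 0.181% ± 0.053 of UMIs against 0.0244% (6 libraries with enough cells, exact two-sided sign-flip test, adjusted p = 0.0343). Endodermal epithelium-like cells gave collagens 0.322% ± 0.0614 against 0.121%, higher in 13 of 13 libraries (exact two-sided sign-flip test, adjusted p = 0.000568). Ribosomal protein genes took 30.5% ± 4.43 of UMIs in progenitor-like cells against 20.1% elsewhere, proteasome genes 0.747% against 0.463%, and in gland-like cells lysosomal genes took 3.10% against 1.23%. Ectodermal epithelium-like cells gave actomyosin genes 0.933% against 0.589% and adhesion genes 0.409% against 0.282%. Both lists share members with the epitheliomuscular markers, whose summed log2 ratio above -0.5 was needed for this name. Naming thus favoured the direction of these differences. Of 135 tested pairs of list and class, 28 were higher and 96 lower in the class. By the median log2 fold of the members instead of their sum, 15 pairs were higher and 109 lower, 8 pairs were called in opposite directions by the 2 measures, and the Notch list in nematoblast-like cells and the lysosomal list in gland-like cells turned negative, at -0.142 and -1.54.

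The ATAC-seq consensus list held 76476 peaks on 3603 scaffolds, covering 41.8 Mb. Peaks had a median width of 476 bases (quartiles 309 and 703) and a median gap of 5282 bases to the next peak on the scaffold. The 211 scaffolds with over 100 peaks carried 46.1% of all peaks, and 960 scaffolds carried 1 peak each. Because replicates were merged into 1 list and the score is constant at 1000, the 3 replicates could not be compared. The genome build is not given in the sources used here, so peaks were not assigned to genes.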

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

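Tests on GFP were chosen only after the result was seen.

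A signal appeared outside the main measurement, on genome gene models, which served only as an alternative: whole-animal libraries 1 to 6, whose labels name no reporter, held 299 GFP UMIs, and female 1 and male 1, also without such a label, held 397 and 297. The clusters that carry GFP in the sorted libraries held 52.0% of the UMIs of libraries 1 to 6 in clustered cells, 103 of these 144 in the progenitor-like cluster 5, and 3.68% of all UMIs, a ratio of 14.1 (10.6 to 17.5 with cells resampled). Free RNA would follow all UMIs and give a ratio near 1. Single libraries gave 4.39 to 20.9 and the clusters without cluster 5 gave 22.2, so free RNA is not borne out. Reads given to the wrong library keep the barcode of their source cell and need not follow all UMIs. The ratio therefore cannot decide on misassigned reads. The 5 libraries of D06 and D11 without a reporter label held 0 GFP UMIs on genome gene models. The rate of libraries 1 to 6, which held 31 to 68 each, predicts 194. This argues against a Hydra gene counted on the reporter sequence at a like rate in all libraries as the source of the 299 UMIs. On the transcriptome the 5 libraries held 14 where 64.5 are predicted, so such a gene is left open for a part there. The ratio of 14.1 is in line with reporter cells among the dissociated animals, and no group in the design tests a biological explanation.

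A difference between groups was found for the sexes: 162 genes differed in the direct edgeR test of male against female libraries, 140 higher and 22 lower in males, against 0 in D03 and D06 only and 13 to 1196 with 1 library left out.

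Among the 9 whole-animal libraries alone, Dixon's rule marked a library as far from the others in 0 of 13 measures.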

How the results depend on the processing

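Over 22 results with 164 alternatives, 96 kept direction and side of the threshold or stayed within 1.5 times, 10 lost a call, 1 gained it, 4 reversed and 53 moved further. Of 3251 alternatives for 382 named genes, 2869 kept the call, 382 lost it and 0 reversed. Where no cause is given below, the cause was not tested.

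With DESeq2, genes higher and lower in males were 427 and 299, those lower in females 934, and those between the sexes 416. Without a filter, which tests more genes, these were 675 and 501 (males), 846 and 1200 (females) and 798, with 1067 in neuron-like cells. Without the preparation term, 34 were lower in males, 329 lower in females and 101 differed between the sexes. In D03 and D06 only, the counts were 4 and 0, 0 and 0, and 0. That fit had fewer libraries and took no spread from the unsexed libraries of D01, D02 and D11. On genome gene models, 112 and 35 (males), 377 lower in females and 95 between the sexes were called, and 2142 and 2702 in sorted libraries.

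Leaving out 1 library, with the lone library assumed to vary like the others, gave 113 to 483 genes higher and 28 to 198 lower in males, 204 to 960 higher and 218 to 879 lower in females, and 13 to 1196 between the sexes. It gave 2387 to 2427 higher and 2621 to 2738 lower in sorted libraries and 9 to 14 in neuron-like cells. Neuron-like cells gave 80 genes at resolution 0.5, 418 at resolution 2, 72 with all cells, 1715 without Scrublet's calls and 62 without its highest 5% of scores, each with the cells clustered and named anew. Camera with an estimated correlation called 1 list and fry 15.

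The neuron-like difference was 41.27 to 44.07 percentage points with a library left out (exact p = 0.1, the smallest possible), and -7.968 (exact p = 0.1636) for at least 3 markers at full depth. Resolution 2 gave 0.3303 for sperm lineage-like cells in females (exact adjusted p = 0.02424). Without precedence, the germline-like difference was 0.08493 in females and -0.2836 in males, and the sperm lineage-like one in males 17.15 (exact adjusted p = 0.07273). Exchanged only within D03 and D06, the differences were 18.93 for germline-like cells in females and 17.04 for sperm lineage-like cells in males (exact adjusted p = 1, with 4 arrangements too few for a call). Leaving out a library gave 7.405 to 30.72 and -1.657 to 4.292 for germline-like cells in females and males, and -0.08586 to 2.142 and 10.13 to 24.18 for sperm lineage-like cells.

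By the median of members, 15 pairs of list and class were higher and 109 lower, and 8 were called in opposite directions by the 2 measures. The sign turned for the lysosomal list in gland-like cells (-1.54), the Notch list in nematoblast-like (-0.142) and neuron-like cells (-0.268) and transcription factors in neuron-like cells (-0.525), among others. At an average log2 CPM of at least 5, Pearson's r between assays was 0.91, Spearman's rho 0.604 and the same sign held in 87.7% of 594 genes called in both. Tag-seq replicates share only a number: as a block it gave 2324 and 2589 genes, and deviations of same-numbered pools correlated at 0.0734, 0.00544 and -0.106. A block on replicates 1 and 2 gave 3811 and 3885 genes in sorted libraries. Depth per cell was lowest in the sorted libraries, with 907 and 895 median UMIs.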

Other observations

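List shares in further classes were taken as percent of UMIs within the unsorted libraries (exact two-sided sign-flip tests). Neuron-like cells gave transcription factors 0.221% against 0.129% in other cells and Notch genes 0.044% against 0.0235%, while the median log2 fold of the members was -0.525 and -0.268. Endodermal epithelium-like cells gave innate immunity genes 0.31% against 0.159%, BMP and TGF-beta genes 0.09% against 0.042% and cell cycle genes 0.0859% against 0.193%. Germline-like cells gave proteasome genes 0.733% against 0.474%.

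Tests on the brine shrimp matches and on regrouped libraries were chosen only after the results were seen.

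Transcripts whose best match is a brine shrimp protein were higher in endoderm pools, with the 5 matches together at 1010, 33.1 and 72.5 CPM in replicates 1, 2 and 3 and at most 1.63 CPM in ectoderm. If RNA of food animals in the gut were the source, the members would keep their ratio; shares differed between endoderm libraries by up to 19.8 percentage points, for RLA2_ARTSA (t3342aep) at 8.72% to 28.6%, and by up to 7.79 among the 4 mitochondrial members alone. Expression by endodermal epithelial or gland cells would put this nuclear match into those Drop-seq classes, and it stood there at 0.562 CPM (95% upper limit 0.768), against 9.45 CPM in the lowest endoderm pool, which speaks against it. The difference of 19.8 points leaves the food source open. Animals of the pools and of Drop-seq were not the same, and feeding before sampling is not given in the sources used here.

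For the lists higher in endoderm, gland cells within the pools were weighed against expression by the epithelium, with gland markers left out and the digestive enzymes, all of which are gland markers, not weighed. Gland-like cells held a median of 98.2% of the UMIs shared with endodermal epithelium-like cells for metalloproteinases and astacins, but 7 of 12 members lay over 75% and 5 under 25%, which leaves that list open. Equal expression would give 23.0%. Medians of 2.53% for lysosomal hydrolases, 1.93% for collagens and 6.15% for innate immunity genes speak against gland cells for most members there. Of 31 lysosomal members 4 lay over 75% and 27 under 25%. Summed lysosomal UMIs took a larger share in gland-like than in other cells. The axonemal median was 20% (upper quartile 24.8%), under the 25% set beforehand. Of 42 axonemal members 0 lay over 75%, and the highest stood at 36.0%. These values argue against gland cells as their main source, while a median near 23.0% leaves a smaller part open. With the genes that named the classes left out, 97 called members were tested in single cells. Of these, 94.8% were also higher in endodermal than in ectodermal epithelium-like cells, against 80% of 1910 other genes called higher in endoderm. Naming the classes with Tag-seq genes favoured this direction for listed and other genes. For the cell cycle list in ectoderm, 8 called members were weighed, with progenitor markers left out. Progenitor-like cells held a median of 62.0% (28.4% to 72.4%) of the UMIs shared with ectodermal epithelium-like cells. Equal expression would give 33.9%. The median lay between the 25% and 75% set beforehand, which leaves their part in it open.

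With the Tag-seq libraries regrouped 3 against 3, 1 of 10 splits, the real one, reached its 4956 called genes and the highest other count was 0; 10 splits are too few to say more. With class labels exchanged within libraries, 1 of 25 draws, the real one, reached 7689 genes between epithelial classes, and the highest other count was 5083.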
